A study of Mus musculus with 6 samples.

How the data were processed

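The deposited values were log2 signals of an Affymetrix array, made by RMA in Affymetrix Expression Console 1.4 per the submitters' processing notes, and they were used as given, with 2 decimals. RNA was amplified with a whole-transcriptome kit before labelling, so that the values describe amplified RNA of sorted cells. All 6 samples entered the fits, save in the alternatives that left samples out, and 0 columns of values were left unused. Of 34390 probe sets, 23521 carried exactly 1 gene symbol, 1814 carried several and 9055 carried none. Those with 1 symbol entered, save in an alternative that tested every probe set on its own, with several symbols or none. For 1082 genes with more than 1 probe set the brightest stood for the gene. Of the probe sets with 1 symbol, 23328 had a gene identifier found in the reference table, and 0 symbols were updated. Genes below the 30th percentile of mean signal, 4.335 on the log2 scale, were left out as dim, which left 15529 of 22180 genes. Where the lower group of a comparison lay below that level, the fold is given as a lower bound. Such a bound concerns the dim signal only and does not allow for the spread between samples.

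Differences were tested in R 4.3.3 with limma 3.58.1, as a model with a mean for each of the 3 subsets, a variance prior with an intensity trend, two-sided moderated tests and Benjamini-Hochberg adjustment over all genes tested. A gene counted as called at an adjusted p below 0.05. The variance of a gene rested on 3 residual degrees of freedom and 5.77 from the prior, and the median standard error of a log2 difference was 0.193. The samples of CX3CR1high cells serve both comparisons that contain them, as do those of the other subsets, so that the comparisons are not independent.

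The calls come from the fit without a term for the replicate number. Whether that number pairs samples across subsets, which the labels left open, was checked in the values. Deviations of the same replicate number from the subset means correlated across genes at 0.146, 0.136 and 0.178 for the 3 pairs of subsets, and at 0.123, 0.113 and 0.158 without sex-linked genes. The female transcript Xist was at 7.39, 7.61 and 7.97 in replicates 1 and at 11.24, 10.99 and 11.39 in replicates 2, and the Y-linked gene Eif2s3y was at 8.27, 7.86 and 7.76 against 2.99, 3.72 and 3.57. Replicates 1 and 2 of every subset thus differed in sex composition, and the spread within a subset includes that difference. The replicate block was therefore run beside each result, with 2 residual degrees of freedom, and it called 154, 47 and 0 genes in the 3 pairwise comparisons.

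Gene lists, 34 in all, were written before the data were examined, as were the comparisons, the filters, the thresholds, the naming of genes and most alternatives. They covered macrophage states and markers of other cells, and 489 of their 576 different genes were tested. Genes on no probe set with a single symbol, 52 of them, were not analysed here. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. Camera shifted 15, 9 and 11 lists in the comparisons of CX3CR1high with CX3CR1low, CX3CR1high with CX3CR1int, and CX3CR1int with CX3CR1low cells. None held with an estimated correlation. With the replicate block, camera at the preset correlation shifted 18, 10 and 11 lists. In its directional form, which asks whether the genes of a list move on balance in the same way, fry called 1, 0 and 0 lists. Its mixed form, which asks for change in either direction, called 13, 10 and 0 lists. The named genes were the 12 largest rises and 12 largest falls among called genes without overlap, up to 4 genes of the smallest p per list, and 9 genes always given. Symbols of clones and those beginning with Mir, Snor or Olfr were passed over, which left small nucleolar RNAs under other symbols, such as Rnu3a, among the genes that could be named. Chosen after seeing the data were a covariate for keratinocyte and fibroblast markers, a fit without non-coding genes, and the tests of the closing part.

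The fit was tested on simulated data, in which 1, 2 or 3 log2 units were added to chosen genes. Between CX3CR1high and CX3CR1low samples it recovered 39.7%, 98.5% and 100% of them, with 10 false calls among 168. The simulated noise was independent between genes and held no effect of the replicate number, unlike these data. The rates therefore hold only for such noise. Changes of 2-fold are therefore often missed at this number of arrays. Fluorescence values of the sort, scan dates and single probe intensities were not used here.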

Results

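Gene expression was measured on arrays in macrophages sorted from the digested ear skin of mice aged 2 weeks. The mice carried the gene for green fluorescent protein in place of a single copy of Cx3cr1, the gene of the fractalkine receptor, which reports the activity of that gene. The 3 sorted subsets were CX3CR1low, CX3CR1int (intermediate) and CX3CR1high cells. Each subset had 2 samples, each pooled from 4 mice, and the subset samples came from 2 independent litters. The 6 arrays had medians between 4.84 and 4.94 on the log2 scale of the normalised signal. The correlation across genes was 0.974 to 0.977 between the 2 samples of a subset and 0.960 to 0.978 between subsets, and genes are not independent replicates. The leading principal component held 33.9% of the variance, and both CX3CR1high samples had the highest scores on it, 30.1 and 13.9. The number of arrays, 2 per subset, limits the precision of every value given here.

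The level of Cx3cr1 itself (probe set 17532268) showed how far the transcript followed the order of the sorted subsets. Cx3cr1 was highest in the CX3CR1high samples, with a log2 signal of 10.03 ± 0.74 (SD, n = 2), against 6.95 ± 0.15 (SD, n = 2) in CX3CR1int and 6.44 ± 0.81 (SD, n = 2) in CX3CR1low samples. It rose 12-fold from CX3CR1low to CX3CR1high cells (log2 difference 3.59 ± 0.41, SE, adjusted p = 0.0163) and 8.49-fold from CX3CR1int to CX3CR1high cells (adjusted p = 0.0421). Between CX3CR1int and CX3CR1low cells Cx3cr1 did not differ by the test (1.42-fold, adjusted p = 0.996), and the CX3CR1low sample 2 (7.01) lay between the CX3CR1int samples (7.05 and 6.84). Genes of macrophage identity did not differ by the test. Adgre1, which encodes the macrophage antigen F4/80, differed by -0.08 between CX3CR1high and CX3CR1low cells on the log2 scale. Csf1r, the receptor of the growth factor on which macrophages depend, differed by -0.14, and the mannose receptor gene Mrc1 by -0.10. Lyve1, a hyaluronan receptor of perivascular macrophages, differed by 0.20, P2ry12, a purine receptor typical of microglia, by 0.04, and H2-Aa, an MHC class II chain, by 0.25. Ccr2, the chemokine receptor of monocytes, was 1.24 higher and Cd207, the Langerhans cell lectin langerin, 1.22 higher, and neither passed (adjusted p = 0.401 and 0.181). The call of Cx3cr1 between CX3CR1high and CX3CR1low cells ended without the CX3CR1low sample 1 (3.02, adjusted p = 0.0553) or the CX3CR1high sample 1 (3.07, adjusted p = 0.154). With the replicate block, a term for the replicate number in the model, Cx3cr1 kept both calls (adjusted p = 0.00798 against CX3CR1low and 0.0255 against CX3CR1int).

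**Figure D1:**
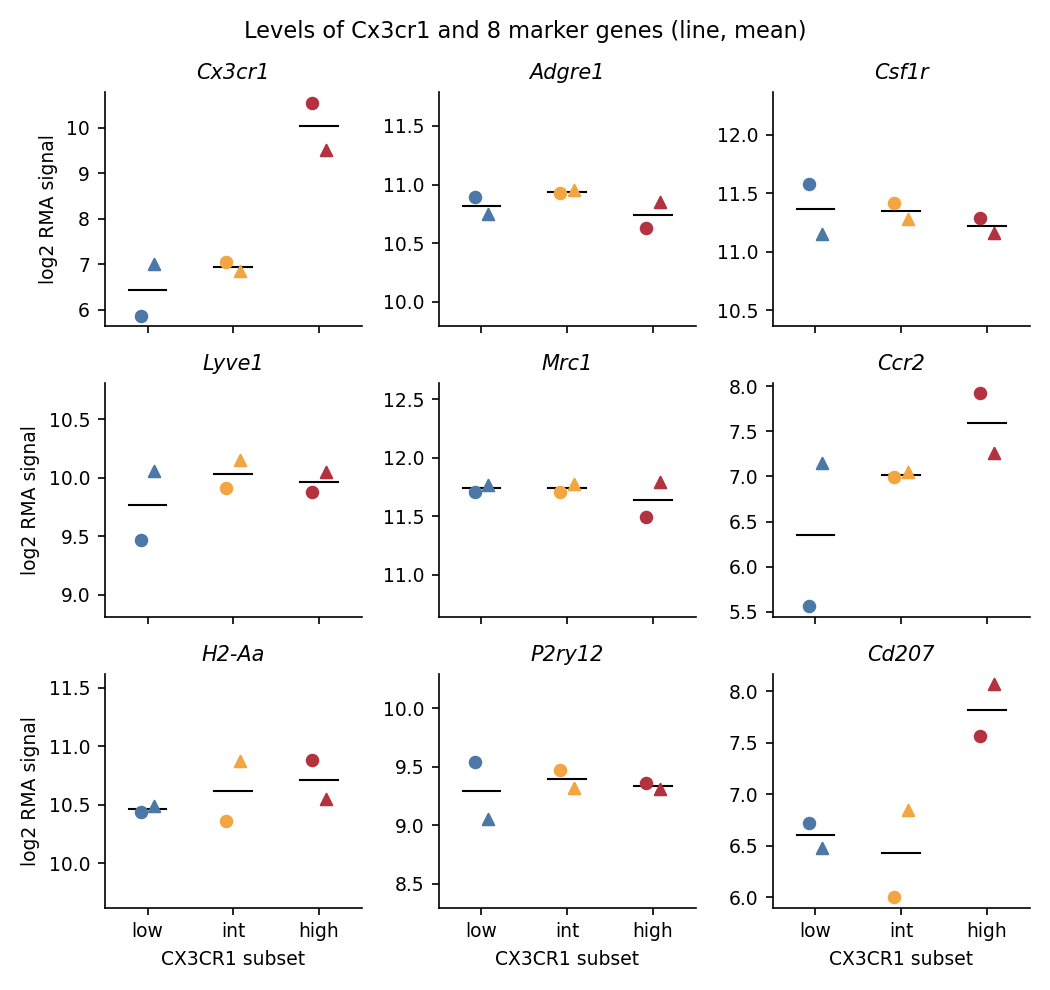
Each panel plots the log2 normalised signal (vertical axis) of a gene in the CX3CR1low, CX3CR1int and CX3CR1high samples (horizontal axis), with a circle for replicate 1, a triangle for replicate 2 and a line at the mean of the 2. Cx3cr1 reached 10.55 and 9.51 in the CX3CR1high samples and at most 7.05 in the others.

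The comparison of CX3CR1high with CX3CR1low cells asked what sets apart the macrophages at the ends of the CX3CR1 range. Genes for adhesion, matrix breakdown and cytokines were among those that rose in CX3CR1high cells. Besides Cx3cr1, the largest rise was that of Clec12a, an inhibitory lectin receptor of myeloid cells, 5.19-fold (log2 difference 2.38 ± 0.24, SE, n = 2 per subset, adjusted p = 0.0103). Bcl2a1a, which protects cells from apoptosis and belongs to a cluster of near-identical genes, rose 4.44-fold (2.15 ± 0.17, SE, adjusted p = 0.00512). F11r, a junctional adhesion molecule, rose 3.99-fold (2.00 ± 0.30, SE), and Ccl22, a chemokine that draws T cells through CCR4, rose 3.80-fold. Mmp13, a collagenase, rose 3.71-fold, and Stap1, a signalling adaptor, rose 3.56-fold. The integrin genes Itgav and Itga6 rose 3.15-fold and 3.06-fold, Tnfsf18, the ligand of the T-cell receptor GITR, 3.13-fold, and Lpcat2, an enzyme of platelet-activating factor synthesis, 3.03-fold. A second, dimmer probe set of Itgav rose by 0.665 on the log2 scale, against 1.655 for the one used. Ndc80, a kinetochore gene of dividing cells, rose 3.20-fold.

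Lectin, complement and peptidase genes were among those that fell in CX3CR1high against CX3CR1low cells. Cd209d and Cd209g, which encode mouse relatives of the lectin DC-SIGN, fell 11.4-fold (log2 difference -3.52 ± 0.29, SE, n = 2 per subset, adjusted p = 0.00512) and 10.1-fold (-3.34 ± 0.34, SE, adjusted p = 0.0103). C4b, a component of complement, fell 7.75-fold, and Retnla, a secreted product of alternatively activated macrophages, fell 6.61-fold (-2.73 ± 0.27, SE). The aminopeptidase gene Enpep fell 5.86-fold, the adhesion receptor gene Adgrg1 5.52-fold, and the membrane protein gene Ms4a8a 4.77-fold. Dnm1, a dynamin best known from neurons, fell 4.61-fold, Tnfrsf17, a receptor best known from plasma cells, at least 4.29-fold, and Gfra2, a receptor of the nerve growth factor neurturin, 4.10-fold. Cpa3 and Mcpt4, mast cell proteases, fell at least 10.3-fold (-3.37 ± 0.27, SE) and 4.77-fold. The CX3CR1high means of Cpa3 (4.07) and Tnfrsf17 (4.28) lay below 4.335, the level under which genes counted as dim. Their folds are therefore lower bounds as far as the dim signal goes, without allowance for the spread between samples. The number of genes called was 62 of 15529 tested, 33 higher and 29 lower, and 60 of them differed at least 2-fold.

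**Figure D2:**
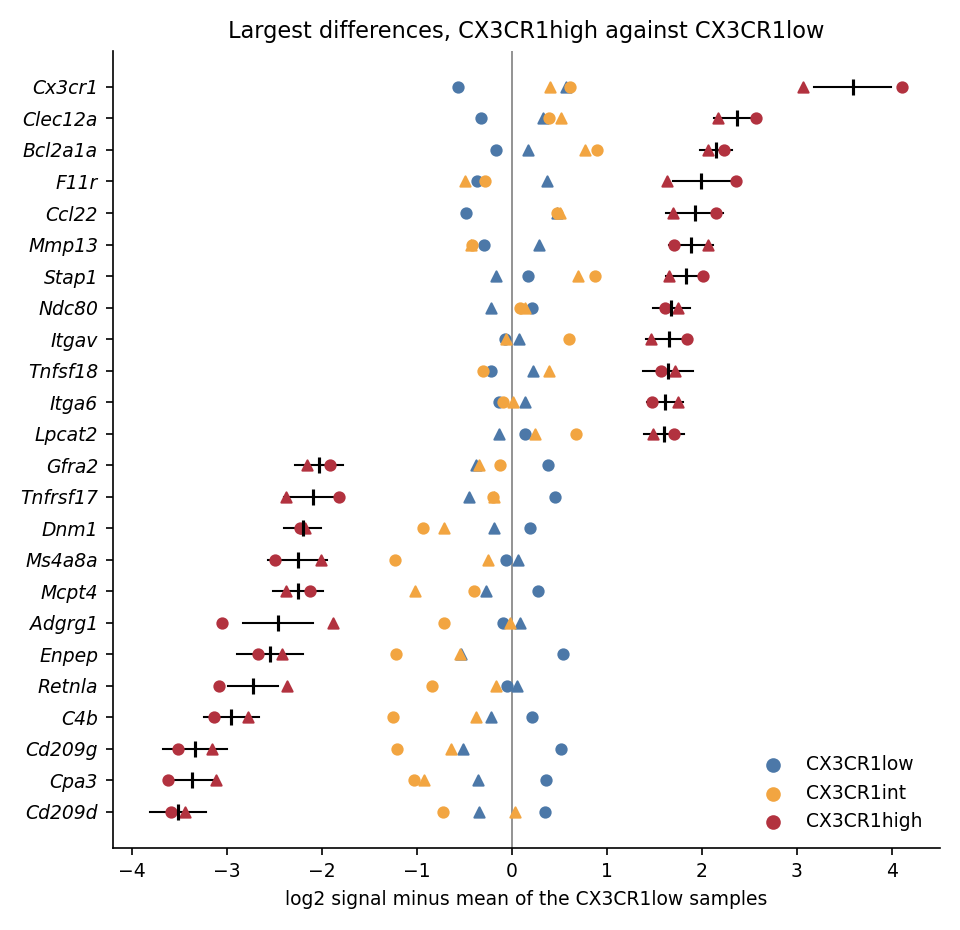
Each row is a gene among the 12 largest rises and 12 largest falls, and the horizontal axis is the log2 signal minus the mean of the CX3CR1low samples. Circles and triangles are replicates 1 and 2, and a black bar spans the difference between CX3CR1high and CX3CR1low cells ± SE, which ran from -3.52 for Cd209d to 3.59 for Cx3cr1.

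Among the fixed gene lists, 4 shifted up in CX3CR1high against CX3CR1low cells. Of 27 tested inflammatory cytokine and chemokine genes, Il1a (1.13), Il10 (1.12), Il1b (0.88) and Ccl22 (1.93) rose among all genes, and 13 were higher and 2 lower adjusted over the list alone. The replicate block raised the calls to 10, 8 higher and 2 lower. The genes called without it include the interleukin 1 pair, which starts inflammation, and Il10, which dampens it. The median of the list was 0.42 (camera adjusted p = 3.98e-08, and adjusted p = 0.318 with an estimated correlation). All 25 tested cell cycle genes were higher, none was called among all genes, 1 was called with the replicate block (Kif11, adjusted p = 0.0427), and 13 passed adjusted over the list alone. The mitotic motor gene Kif11 was higher by 1.11, the topoisomerase gene Top2a by 1.23, and the spindle gene Nusap1 by 1.0. The median of the cell cycle list was 0.71 (camera adjusted p = 1.52e-14, and adjusted p = 0.318 with an estimated correlation). Of 17 tested microglia-type and nerve-associated genes, Cx3cr1 and the chemokine-binding receptor gene Ccrl2 (1.19) rose, 3 were called with the replicate block, and 4 were higher and 1 lower adjusted over the list alone. In direction 13 of the 17 were higher and 4 lower, and P2ry12 of this list did not differ by the test (0.04). Cx3cr1 defined the sorted subsets, so that its part in the shift of this list came from the sort. Olfml3, a secreted matrix protein of microglia, was 1.0 higher and the TGF-beta receptor gene Tgfbr1 0.98 higher (camera adjusted p = 0.00517, and adjusted p = 0.318 with an estimated correlation). Of 14 MHC class II presentation genes 13 were higher, none passed among all genes or adjusted over the list alone, and the co-stimulator gene Cd86 was 0.29 higher (camera adjusted p = 0.00966, and adjusted p = 0.318 with an estimated correlation). The microglia-type call ended without the CX3CR1low sample 2 (median 0.05, adjusted p = 0.22) and with a covariate for keratinocyte and fibroblast markers (-0.11, adjusted p = 0.733). The MHC class II call ended without the CX3CR1low sample 1 (adjusted p = 0.167) or the CX3CR1high sample 1 (median 0.09, adjusted p = 0.264). Without the CX3CR1high sample 2 the cell cycle median was 0.39.

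State lists that shifted down in CX3CR1high cells numbered 6. Of 21 tested genes of perivascular-type resident macrophages, the lectin genes Cd209d, Cd209g, Cd209b (-1.98) and Clec10a (-1.74) fell, 5 were called with the replicate block, all lower, and 8 were lower adjusted over the list alone. The median of this list was -0.54 (camera adjusted p = 5.43e-11, and adjusted p = 0.318 with an estimated correlation). In direction 17 of its genes were lower and 4 higher, and its members Lyve1 (0.20) and Mrc1 (-0.10) did not differ by the test. Of 13 complement genes C4b fell, 6 were lower adjusted over the list alone, among them properdin (Cfp, -1.09) and factor B (Cfb, -1.71), and 1 was higher, the integrin gene Itgax (0.91). Cfp and Cfb were called with the replicate block (adjusted p = 0.0290 and 0.0367). The complement median was -0.31 (camera adjusted p = 0.000102, and adjusted p = 0.318 with an estimated correlation). No lysosome gene of 20 was called, and 1 was lower adjusted over the list alone, the collagen-cleaving cathepsin gene Ctsk (-1.71), which was called with the replicate block (adjusted p = 0.0367). That list had a median of -0.15 (camera adjusted p = 0.00423, and adjusted p = 0.550 with an estimated correlation). Of 23 genes of handling stress and the immediate early response, Rgs1, a regulator of chemokine receptor signalling, rose by 1.36 against the direction of its list, and 2 were higher and 3 lower adjusted over the list alone. The median was -0.20 (camera adjusted p = 0.00517, and adjusted p = 0.362 with an estimated correlation). Of 16 transmitter and purine receptor genes, Adgrg1 fell, itself an adhesion receptor and not a transmitter receptor, and 5 were lower adjusted over the list alone (median -0.08, camera adjusted p = 0.0493, and adjusted p = 0.318 with an estimated correlation). None of 19 interferon response genes passed in either way, and the antiviral gene Rsad2, 1.09 lower, was called with the replicate block (adjusted p = 0.0356). The interferon median of -0.33 (camera adjusted p = 0.0127, and adjusted p = 0.752 with an estimated correlation) turned to 0.46 with a covariate for keratinocyte and fibroblast markers. Its test also turned without the CX3CR1low sample 2 (-0.06), and its call ended without the CX3CR1high sample 1 (adjusted p = 0.523). The lysosome call ended without the CX3CR1low sample 1 (adjusted p = 0.0546), without the CX3CR1high sample 1 (0.110) and with the covariate (0.207). That of handling stress ended without the CX3CR1high sample 2 (median -0.11) and with the covariate, where the median was -0.209 (camera adjusted p = 0.0674). The transmitter call ended without the CX3CR1low sample 2 (median -0.168), either CX3CR1int sample (-0.0825, unchanged) or the CX3CR1high sample 2 (no shift of the median). It also ended with the covariate (-0.243, camera adjusted p = 0.531). The transmitter median was -0.28 without the CX3CR1low sample 1 and -0.185 without the CX3CR1high sample 1. Without the CX3CR1low sample 1 the complement median was -0.12 and the perivascular-type median -0.33. The complement median was -0.485 without the CX3CR1low sample 2 and -0.519 with the covariate.

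Markers of other skin cells moved with the falling groups. Of 17 keratinocyte genes the suprabasal keratin gene Krt10 fell (-1.46 ± 0.23, SE), 3 were called with the replicate block, and 12 were lower adjusted over the list alone, with a median of -0.84 (camera adjusted p = 1.34e-10, and adjusted p = 0.318 with an estimated correlation). None of 14 fibroblast genes was called and 8 were lower adjusted over the list alone, among them the collagen genes Col1a1 (-1.07) and Col1a2 (-1.12) and the proteoglycan gene Dcn (-1.24). In the fit with the replicate block 6 fibroblast genes were called, all lower, among them Col1a1 (adjusted p = 0.0453), Dcn (0.0484) and Pcolce, which aids collagen processing (0.0337). The fibroblast median was -1.04 (camera adjusted p = 1.34e-10, and adjusted p = 0.318 with an estimated correlation). Of 7 mast cell genes Cpa3, Mcpt4 and the chymase gene Cma1 (-1.87) fell, and 4 were lower adjusted over the list alone (median -0.90, camera adjusted p = 7.35e-11, and adjusted p = 0.197 with an estimated correlation). The endothelial list, with the cadherin gene Cdh5 (-1.27) as the only gene lower adjusted over the list alone, shifted down (median -0.20, camera adjusted p = 0.0106, and adjusted p = 0.318 with an estimated correlation). The melanocyte list shifted down without any gene passing either adjustment (median -0.56, camera adjusted p = 0.00349, and adjusted p = 0.318 with an estimated correlation). The mean log2 level of keratinocyte and fibroblast markers was 7.01 and 7.66 in CX3CR1low, 6.59 and 6.82 in CX3CR1int, and 6.45 and 6.6 in CX3CR1high samples. With that mean as a covariate, 8 genes were called, and 2 of them were among the 62. Such a covariate is fitted from differences between the 2 samples of a subset, and replicate 2 had the higher mean in each subset. Its effect therefore cannot be told apart from that of the replicate number. The endothelial call ended without the CX3CR1low sample 2 (median -0.155), without the CX3CR1high sample 2 (-0.105) and with the covariate (-0.185, camera adjusted p = 0.733). The melanocyte call ended without the CX3CR1low sample 2 (adjusted p = 0.0981) and with the covariate (0.498), and the keratinocyte median was -0.53 without that sample.

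Several lists held called genes without shifting as a whole between CX3CR1high and CX3CR1low cells. Among phagocytic and scavenger receptors, the integrin genes Itgav and Itgb5 (1.53) rose and Pros1 (-1.46), a bridge between dying cells and phagocytes, fell, while 4 were higher and 3 lower adjusted over the list alone (camera adjusted p = 0.819). Matrix and protease genes included Mmp13 and the membrane protease gene Mmp14 (1.34), which rose, with 5 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.607). Of the alternative activation genes Retnla and Clec10a fell and Ccl22 rose, with 2 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.135). Sema4d, a semaphorin, rose by 1.11 as the only call among neurotrophic and axon guidance genes, of which 3 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.605). Ccl22 was also the only call among dendritic cell markers, of which 4 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0830). No gene was called on the monocyte list, where Ly6c2 was at least 2.66 lower (adjusted p = 0.0586). The replicate block called 3 of its genes, all lower, among them Ly6c2 (adjusted p = 0.00484) and Gda (0.0337). Of the monocyte genes 1 was higher and 2 lower adjusted over the list alone (camera adjusted p = 0.183). The lists of lipid handling (camera adjusted p = 0.104), cholesterol synthesis (0.0591), the TGF-beta pathway (0.607), macrophage transcription factors (0.996), glycolysis and hypoxia (0.819) and oxidative phosphorylation (0.234) did not shift and held no called gene, but with the replicate block the fatty acid desaturase gene Scd1 (-1.67, adjusted p = 0.0399) and the TGF-beta feedback gene Skil (1.21, adjusted p = 0.0303) were called. No shift was seen in the lists of core macrophage genes (0.996), Langerhans cells (0.471), Schwann cells (0.104), T, NK and innate lymphoid cells (0.904), neutrophils (0.607), B cells (0.148) and erythroid cells (0.607). The replicate block called 5 phagocytic, 3 matrix, 4 alternative activation and 3 dendritic cell genes. With it the lists of monocyte (camera adjusted p = 0.0201), lipid handling (0.0483) and cholesterol synthesis genes (0.0135) shifted down. Median, mean and test differed in sign in the TGF-beta, transcription factor and glycolysis lists.

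The test between CX3CR1high and CX3CR1low cells was a limma fit over all 6 samples, which put 1499 genes at an unadjusted p under 0.05 where 776 were expected by chance. With the replicate block 154 genes were called, 76 higher and 78 lower, and these held all 62. The count was 13 without the CX3CR1low sample 1, 15 without the CX3CR1low sample 2, 39 without either CX3CR1int sample, 0 without the CX3CR1high sample 1 and 16 without the CX3CR1high sample 2. It was 39 with only these 2 subsets in the fit, 26 without the filter on dim genes and 18 with every probe set tested on its own, those with several symbols or none included.

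The comparison of CX3CR1high with CX3CR1int cells asked what changes at the upper step of the CX3CR1 range, where Cx3cr1 itself rose 8.49-fold. Ly6c2, a surface marker of inflammatory monocytes, fell at least 11.2-fold in CX3CR1high cells (log2 difference -3.49 ± 0.45, SE, n = 2 per subset, adjusted p = 0.0421). Its level was 3.36 and 4.92 in CX3CR1high, 7.35 and 7.90 in CX3CR1int, and 6.48 and 7.11 in CX3CR1low samples. The CX3CR1high means of Ly6c2 (4.14), Cpa3 and Cd55 (4.24) lay below the dim level, so that their folds are lower bounds as far as the dim signal goes. These bounds do not allow for the spread between samples, and the CX3CR1high sample 2 of Ly6c2 (4.92) lay above the dim level. Cd209d fell 8.97-fold (-3.17 ± 0.29, SE, adjusted p = 0.0351), Cd209g 5.31-fold, and the mast cell gene Cpa3 at least 5.24-fold. Retnla fell 4.66-fold, C4b 4.41-fold, Gfra2 3.48-fold, the complement inhibitor gene Cd55 at least 3.13-fold, and Dnm1 2.60-fold. F11r rose 5.22-fold (2.39 ± 0.30, SE), Mmp13 4.98-fold (adjusted p = 0.0351), Clec12a 3.78-fold, Itga6 3.15-fold, Ndc80 2.97-fold, the early activation gene Cd69 2.83-fold, and Bcl2a1a 2.49-fold. Rab26os, a long RNA antisense to Rab26, rose 2.91-fold, Snhg5, a host of small nucleolar RNAs, 2.54-fold, and Ddx5, an RNA helicase, 2.27-fold. In all, 12 genes were higher and 10 lower, each at least 2-fold. The microRNA genes Mir677 (higher) and Mir1898 (lower) were among them and are named after their values were seen.

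Inflammatory genes had the largest upward median between CX3CR1int and CX3CR1high cells. None of the 27 was called among all genes, 2 were called with the replicate block, among them Il10 (adjusted p = 0.0346), and 15 were higher and 2 lower adjusted over the list alone, with Il10 1.06 higher, Il1a 0.70 higher and the neutrophil-attracting chemokine gene Cxcl2 0.48 higher (median 0.51). That shift had a camera adjusted p = 9.63e-09, and adjusted p = 0.312 with an estimated correlation. Of 25 cell cycle genes 24 were higher and none passed either adjustment, with Cdk1, the kinase that starts mitosis, 0.79 higher (median 0.31, camera adjusted p = 1.78e-05, and adjusted p = 0.796 with an estimated correlation). Of the microglia-type genes Cx3cr1 rose, and 4 were higher adjusted over the list alone, such as Olfml3 (0.96) and Tgfbr1 (0.94) (camera adjusted p = 0.0312, and adjusted p = 0.796 with an estimated correlation). The part of Cx3cr1 in that shift again came from the sort. The perivascular-type list shifted down, Cd209d and Cd209g fell, 3 were called with the replicate block, and 9 of its 21 genes were lower adjusted over the list alone (median -0.43, camera adjusted p = 9.63e-09, and adjusted p = 0.796 with an estimated correlation). Complement shifted down with C4b, and 1 gene was higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0121, and adjusted p = 0.796 with an estimated correlation). Of 17 monocyte genes Ly6c2 fell and 3 were lower adjusted over the list alone, with the guanine deaminase gene Gda 1.23 lower and Ms4a4c, a membrane protein of inflammatory monocytes, 1.42 lower. The monocyte median was -0.74 (camera adjusted p = 0.00424, and adjusted p = 0.796 with an estimated correlation). Lysosome genes shifted by a median of -0.14 with no gene passing either adjustment, Ctsk being 0.97 lower (camera adjusted p = 0.0390, and adjusted p = 0.907 with an estimated correlation). Beside these falls, Cpa3 fell, 2 mast cell genes were called with the replicate block, and 4 of 7 mast cell genes were lower adjusted over the list alone (median -0.49, camera adjusted p = 2.33e-07, and adjusted p = 0.312 with an estimated correlation). Fibroblast genes shifted by -0.32 with no gene passing either adjustment (camera adjusted p = 0.0205, and adjusted p = 0.907 with an estimated correlation). Keratinocyte genes, with a median of -0.14, did not shift (camera adjusted p = 0.368). Interferon response genes shifted down only with the replicate block (camera adjusted p = 0.0266, against 0.0921 without it). Langerin (Cd207) was 1.4 higher in CX3CR1high than in CX3CR1int cells and did not pass among all genes (adjusted p = 0.190), but it passed adjusted over the Langerhans list alone, as it did against CX3CR1low cells. The cell cycle shift rested on the CX3CR1high sample 2, without which its median was 0.08 (adjusted p = 0.442). Without the CX3CR1int sample 2 the calls of the complement, lysosome, monocyte, fibroblast and microglia-type lists ended. Medians were then -0.265 for complement (-0.27 with all samples) and 0.19 for microglia-type genes (0.165 with all samples). They were -0.085 for lysosome, -0.31 for monocyte and -0.253 for fibroblast genes. The monocyte median was -1.15 without the CX3CR1int sample 1 and -0.415 without the CX3CR1high sample 1. The microglia-type call also ended without the CX3CR1int sample 1 (adjusted p = 0.0769) or the CX3CR1high sample 1 (0.0957). The fibroblast call ended without the CX3CR1high sample 1 (adjusted p = 0.134), and that of the lysosome list without that sample (0.400), the CX3CR1low sample 1 (0.0539) or the CX3CR1low sample 2 (0.0531). With the covariate for keratinocyte and fibroblast markers, the calls of the microglia-type (adjusted p = 0.219), lysosome (0.0868) and monocyte lists (0.0609) ended. Their medians were then -0.0129, -0.15 and -0.396. Without the CX3CR1high sample 1 the perivascular-type median was -0.27.

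The limma fit put 1226 genes at an unadjusted p under 0.05 between CX3CR1high and CX3CR1int cells, and with the replicate block 47 genes were called, 22 higher and 25 lower, all 22 of the main calls among them. The count was 0 without the CX3CR1int sample 1 or the CX3CR1high sample 1, 1 without the CX3CR1int sample 2 and 2 without the CX3CR1high sample 2. It was 14 with only these 2 subsets in the fit, 4 without the intensity trend, 4 with quantile normalisation repeated, and 0 without the filter on dim genes, with every probe set, or with arrays centred on their median. The call of Cx3cr1 ended under each of these but the fit to 2 subsets, and also with a robust fit (adjusted p = 0.0649).

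The comparison of CX3CR1int with CX3CR1low cells asked about the lower step of the range, where Cx3cr1 did not differ by the test. Ddx5, an RNA helicase of splicing and transcription, was the only gene called, 3.28-fold lower in CX3CR1int cells (log2 difference -1.71 ± 0.16, SE, n = 2 per subset, adjusted p = 0.0426). Its level was 8.72 and 8.84 in CX3CR1int against 10.41 and 10.58 in CX3CR1low samples. Genes with the next smallest p did not pass. The mitotic motor gene Kifc1 was 1.28 higher (adjusted p = 0.295), Ccr7, which guides dendritic cells to lymph nodes, 1.09 higher (adjusted p = 0.637), Bcl2a1a 0.84 higher, the orphan receptor gene Gpr141 at least 1.35 higher from a dim level, and Ahcy, an enzyme of methionine metabolism, 0.94 higher. Rab26os was 1.34 lower (adjusted p = 0.295), Rnu3a, a small nucleolar RNA, 2.16 lower (adjusted p = 0.317), Fgfbp1, a carrier of fibroblast growth factors, 1.12 lower, and the cartilage matrix gene Ucma 1.16 lower. The limma fit put 759 genes at an unadjusted p under 0.05, where 776 were expected by chance. With the replicate block no gene was called, and Ddx5 had an adjusted p = 0.0503. The call of Ddx5 ended without any 1 of the 6 samples. Leaving out a CX3CR1high sample cannot change this difference and only weakens the estimate of the spread. The ended calls therefore do not show that the difference of Ddx5 rests on a particular sample.

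Gene lists shifted between CX3CR1int and CX3CR1low cells, where none of their genes was called among all genes, and each shift named in this paragraph had an adjusted p = 0.730 with an estimated correlation. Cell cycle genes were higher in 23 of 25 cases, with Nusap1 0.93 and the nucleotide reductase gene Rrm2 0.81 higher, and none passed adjusted over the list alone (median 0.29, camera adjusted p = 1.06e-06). A second, dimmer probe set of Rrm2 was 0.13 higher. Monocyte genes had a median of 0.23, with Plac8, a small protein of myeloid cells, 1.09 and Ly6c2 0.83 higher, and none passed adjusted over the list alone (camera adjusted p = 0.0362). Without the CX3CR1low sample 1 that median was -0.10, and without the CX3CR1int sample 2 its call ended (0.06, adjusted p = 0.968). Keratinocyte genes had a median of -0.55, and 5 of 17 were lower adjusted over the list alone, among them Krt10 (-1.03) and the desmosome gene Dsg1a (-1.14) (camera adjusted p = 2.06e-11). Fibroblast genes had a median of -0.68, and 5 of 14 were lower adjusted over the list alone, with Col1a1 0.67 lower and the proteoglycan gene Lum 0.86 lower (camera adjusted p = 1.33e-08). Mast cell genes had a median of -0.50, and 2 of 7 were lower adjusted over the list alone, with Cpa3 0.98 and Cma1 0.82 lower (camera adjusted p = 0.000215). Melanocyte (median -0.39, camera adjusted p = 0.00968), Langerhans cell (-0.34, 0.0205) and endothelial genes (-0.16, 0.0385) also shifted down with none passing adjusted over the list alone, and Cldn1, a tight junction gene of the Langerhans list, was 0.71 lower. Among state lists, handling stress genes shifted down, with the immediate early gene Fos 0.58 lower (median -0.15, camera adjusted p = 0.00438). Of the cholesterol synthesis genes 13 of 14 were lower, with the lanosterol synthase gene Lss 0.36 lower (median -0.20, camera adjusted p = 0.0245). Perivascular-type genes, with Cd209g 0.93 lower, shifted as well (median -0.12, camera adjusted p = 0.0466). None of these state genes passed adjusted over the list alone. The cholesterol median turned to 0.07 without the CX3CR1low sample 1 and was 0.02 without the CX3CR1int sample 2 (adjusted p = 0.449). The perivascular-type median turned to 0.02 without the CX3CR1int sample 1, and its call ended without the CX3CR1low sample 1 (adjusted p = 0.623) or with the keratinocyte and fibroblast covariate (0.224). Without the CX3CR1low sample 2 the fibroblast median was -0.20, the keratinocyte median -0.31 and the melanocyte median -0.17 (adjusted p = 0.250, its call ended). The Langerhans median was then -0.05 (adjusted p = 0.910), and it turned to 0.22 with the covariate. Calls also ended without the CX3CR1int sample 1 for Langerhans (adjusted p = 0.413) and endothelial genes (0.153), without the CX3CR1int sample 2 for melanocyte (0.224) and endothelial genes (0.0643), and without the CX3CR1low sample 1 for handling stress genes (0.0558). The endothelial call ended as well without the CX3CR1low sample 2 (adjusted p = 0.500) and with the covariate (0.860), which also ended the melanocyte call (0.541). The mast cell median was -0.26 without the CX3CR1int sample 1. For the cell cycle list the median was 0.17 without the CX3CR1low sample 2 and 0.185 without the CX3CR1int sample 1.

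**Figure D3:**
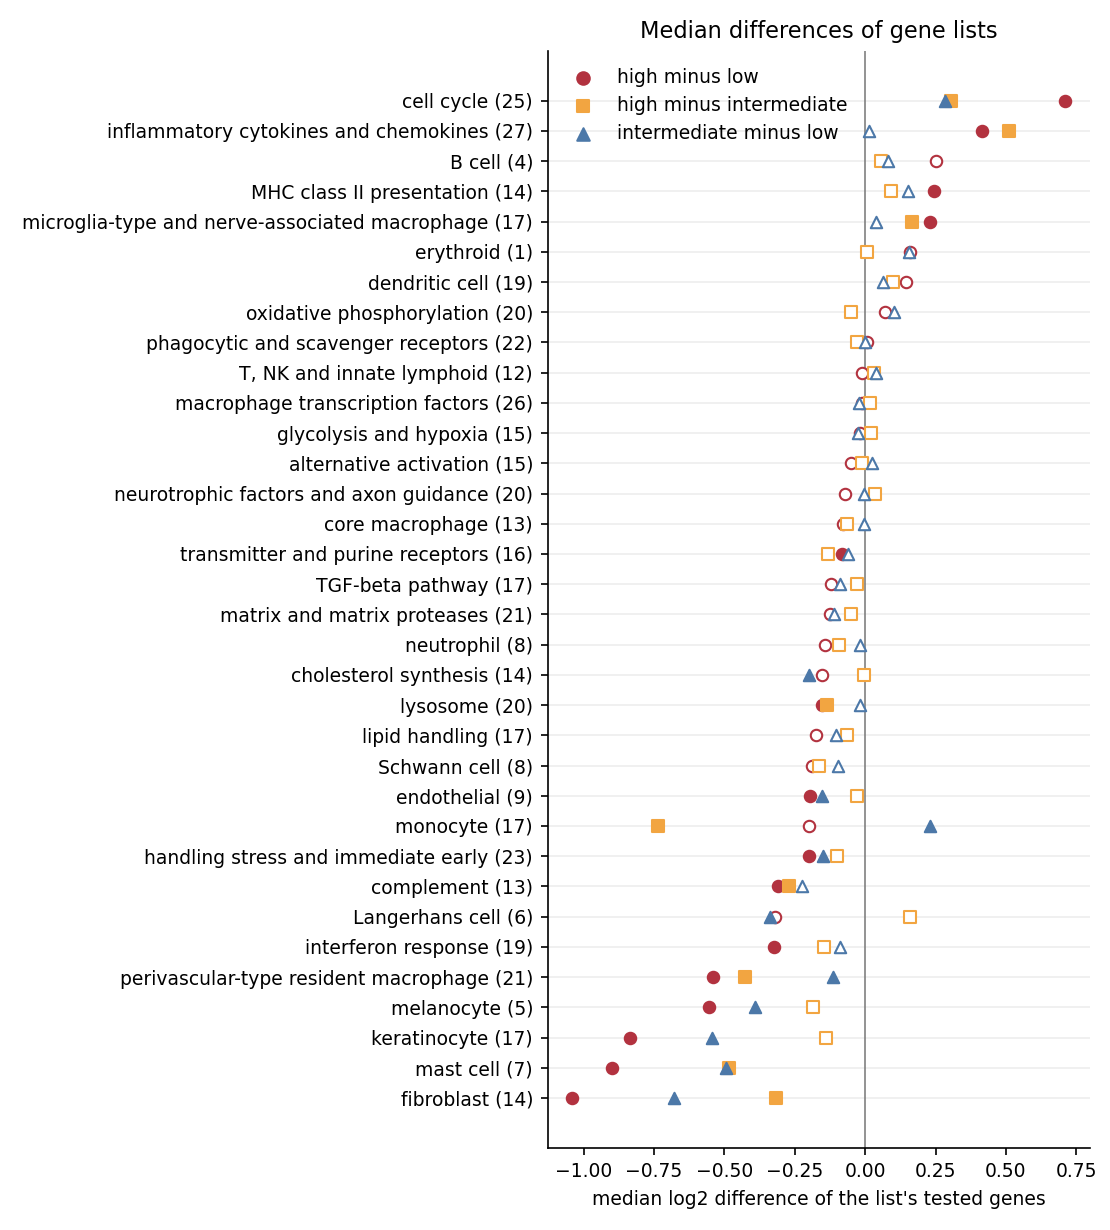
The horizontal axis is the median log2 difference of each gene list, with the number of tested genes in brackets, for CX3CR1high minus CX3CR1low (circles), CX3CR1high minus CX3CR1int (squares) and CX3CR1int minus CX3CR1low cells (triangles), filled where the camera adjusted p was below 0.05. The fibroblast list had the lowest median (-1.04) and the cell cycle list the highest (0.71), both between CX3CR1high and CX3CR1low cells.

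A further contrast asked whether CX3CR1int cells lay at the midpoint of the other subsets or off it. Ddx5 was 2.73-fold below the midpoint (log2 difference -1.45 ± 0.14, SE, n = 2 per subset) and had the smallest adjusted p of all genes, 0.0518. Cx3cr1 was 1.29 below the midpoint on the log2 scale and did not pass (adjusted p = 0.775). No gene passed in the limma fit, which put 849 genes at an unadjusted p under 0.05 where 776 were expected by chance. With the replicate block 3 genes were called, 1 above and 2 below the midpoint, and these were Ly6c2 (at least 2.16, adjusted p = 0.0308), Ddx5 (adjusted p = 0.0308) and Rab26os (-1.44, adjusted p = 0.0308). Ly6c2 and Rab26os are named here after their values were seen. Without the CX3CR1int sample 2 the count was 1.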

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

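Every setting below was fixed before the data were examined, save a covariate for keratinocyte and fibroblast markers and a fit without non-coding genes, which were chosen after the result was seen, and the cause was not tested for any change. The 62 genes called between CX3CR1high and CX3CR1low cells became 154 with the replicate block, 39 with only the 2 subsets in the fit, 26 without the filter on dim genes, 18 with every probe set, 124 at an adjusted p of 0.1, 8 with the covariate, and 0 to 39 with 1 sample left out. The 22 between CX3CR1high and CX3CR1int cells became 47 with the replicate block, 14 with 2 subsets, 4 without the intensity trend, 4 with quantile normalisation repeated, 0 without the filter, with every probe set or with arrays centred on their median, 48 at an adjusted p of 0.1, and 0 to 17 with 1 sample left out. The single call between CX3CR1int and CX3CR1low cells became 0 with the replicate block, 2 subsets, no trend, no filter, every probe set, centred arrays or any 1 sample left out, and 2 with the covariate, Ddx5 not among them. Off the midpoint 3 genes were called with the replicate block, 1 each with a robust fit, array weights, the 50th percentile as filter, the mean of probe sets or no non-coding genes, 2 at an adjusted p of 0.1, and 0 to 1 with 1 sample left out. Cx3cr1 lost its call against CX3CR1low with the covariate (4.46, adjusted p = 0.127), and ran from 3.02 to 4.16 with 1 sample left out. Against CX3CR1int its call ended without the trend, with a robust fit, without the filter, with every probe set and with quantile normalisation (3.09 in each) and with centred arrays (3.05), and it ran from 2.57 to 3.61 with 1 sample left out. Between CX3CR1int and CX3CR1low it ran from -0.065 to 1.07. An estimated correlation left 0, 0 and 0 gene lists of the 15, 9 and 11, and directional fry 1, 0 and 0. With the replicate block they became 18, 10 and 11. With the covariate, which left out the keratinocyte and fibroblast lists, the balance of list directions inverted between CX3CR1high and CX3CR1low, from 4 up and 11 down to 7 up and 4 down (7 of the 15 shared), and between CX3CR1int and CX3CR1low, from 2 up and 9 down to 6 up and 3 down (5 of the 11 shared). Changes with the covariate cannot be read as effects of keratinocyte or fibroblast RNA, because the marker mean was higher in replicate 2 of every subset. The 9 lists of CX3CR1high against CX3CR1int, 3 up and 6 down, became 5 with the covariate, 2 up and 3 down, and 4 to 10 with 1 sample left out, 4 without the CX3CR1int sample 2. Of the single list shifts, 12 lost their call with the covariate while their test kept its direction. These were the microglia-type, lysosome, transmitter, handling stress, endothelial and melanocyte lists between CX3CR1high and CX3CR1low, the microglia-type, lysosome and monocyte lists between CX3CR1high and CX3CR1int, and the perivascular-type, endothelial and melanocyte lists between CX3CR1int and CX3CR1low. The Langerhans list between CX3CR1int and CX3CR1low also lost its call (camera adjusted p = 0.183), and its test turned. None of the 56 results for called genes named in the text changed direction under any setting, though all 56 lost their call without the CX3CR1high sample 1. With 1 sample left out a call can end from lost power alone. The groups of these genes did not overlap, so that leaving out 1 sample could not turn a direction. Nor could the replicate block or the settings of the variance prior, which leave the differences themselves unchanged. Apart from the counts given, the replicate block ended no call but that of Ddx5. Directions turned only for genes not called and for some lists. With the covariate, Mrc1 (0.0633) and P2ry12 (-0.546) turned against CX3CR1low, Lyve1 (0.103) turned in CX3CR1high against CX3CR1int, and P2ry12 (-0.356) in CX3CR1int against CX3CR1low. So did the lists of the interferon response (0.456, camera adjusted p = 2.11e-06) and Langerhans cells (0.223). The mean of interferon genes was likewise higher in replicate 2 of CX3CR1low (7.585 against 7.011), CX3CR1int (7.462 against 6.924) and CX3CR1high cells (7.224 against 6.786). Centred arrays turned P2ry12 (-0.005) in CX3CR1high and Mrc1 (-0.005) in CX3CR1int against CX3CR1low, and quantile normalisation turned Mrc1 (-0.00667) in the latter. With 1 sample left out, CX3CR1high against CX3CR1low ran from -0.19 to 0.03 for Adgre1, -0.355 to 0.075 for Csf1r, -0.095 to 0.495 for Lyve1, -0.25 to 0.05 for Mrc1 and -0.205 to 0.285 for P2ry12. CX3CR1high against CX3CR1int ran from -0.185 to 0.055 for Lyve1, -0.255 to 0.045 for Mrc1, -0.155 to 0.355 for H2-Aa and -0.135 to 0.015 for P2ry12. CX3CR1int against CX3CR1low ran from -0.23 to 0.2 for Csf1r, -0.03 to 0.56 for Lyve1, -0.03 to 0.04 for Mrc1, -0.13 to 1.46 for Ccr2, -0.105 to 0.405 for H2-Aa, -0.145 to 0.345 for P2ry12 and -0.6 to 0.25 for Cd207. Among lists, the interferon median ran from -0.565 to -0.06 between CX3CR1high and CX3CR1low, where its test turned at the upper end. Between CX3CR1int and CX3CR1low the perivascular-type median ran from -0.225 to 0.015, that of cholesterol synthesis from -0.615 to 0.0675 and that of monocyte genes from -0.095 to 0.765.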

Other observations

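The genes, contrasts and tests of this part were chosen only after the result was seen. With the replicate block, which removes what the samples of a replicate number share, 92 further genes were called between CX3CR1high and CX3CR1low cells, 43 higher and 49 lower. Among the higher ones were Axl, a receptor for the uptake of dying cells (2.90-fold, log2 difference 1.53, adjusted p = 0.0305), and Cd93, a receptor linked to adhesion and clearance (2.81-fold). Ccr7, which guides cells to lymph nodes, and Icosl, a co-stimulator of T cells, were each 2.49-fold higher. The chemokine genes Ccl5 and Cxcl10 were 2.44-fold and 2.10-fold higher, and the prostaglandin synthase gene Ptgs2 was 2.39-fold higher. Genes of dividing cells, Kif11, Knl1 and E2f8, were 2.15-fold, 2.03-fold and 2.32-fold higher. Among the lower ones Ly6c2 was at least 6.3-fold lower (-2.66, adjusted p = 0.00484), and the chemokine genes Ccl6 and Ccl8 were 3.05-fold and 2.94-fold lower. The complement gene Cfb was 3.27-fold lower, the cathepsin gene Ctsk 3.26-fold and the scavenger receptor gene Cd163 1.87-fold lower. Matrix genes of fibroblasts were lower beside them, with Aspn 3.4-fold, Dcn 2.36-fold and Col1a2 2.17-fold lower. Between CX3CR1high and CX3CR1int cells the block added 25 genes, 10 higher and 15 lower, such as Tnfsf18 (3.03-fold higher), Itgav (2.61-fold higher) and Adgrg1 (4.29-fold lower).

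The genes that were lower in CX3CR1high than in CX3CR1low cells might reflect RNA of other skin cells in the CX3CR1low samples, since keratinocyte, fibroblast and mast cell markers were lower too. A sort for macrophages should remove such cells, and the marker lists were written before the data were examined. In the 25 lower genes outside those lists, such as Cd209d, Retnla and C4b, a median of 24% of the fall had already occurred in CX3CR1int cells (quartiles 13.4 to 32.8%), against 70.2% (quartiles 62.3 to 84.5%) in the 15 keratinocyte and fibroblast markers that were lower by at least 1 log2 unit. From CX3CR1int to CX3CR1high cells these genes differed by a median of -1.515 and those markers by -0.4 (all tested keratinocyte genes by -0.14, all fibroblast genes by -0.32), so that RNA from keratinocytes or fibroblasts does not account for that step, while the step from CX3CR1low to CX3CR1int cells (-0.41 against -0.865) stays open. Against RNA from mast cells the same 24% decides nothing, because the 3 called mast cell markers had 29.1 to 43.7% and the ranges overlap, so that mast cell RNA and a difference between macrophage subsets cannot be told apart.

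Small nucleolar RNA genes, which guide the modification of ribosomal RNA, tended to be lower in CX3CR1int samples than the mean of both other subsets. None of them passed off the midpoint in the limma fit, and the set was not tested as a whole. Their median in the CX3CR1int sample 1 (5.95) lay close to that in the CX3CR1low sample 1 (6.0). Of 60 such genes 48 were lower, with a median difference of -0.37 on the log2 scale and sample medians of 5.95 and 5.63 in CX3CR1int against 6.03 to 6.04 in CX3CR1high and 6.0 to 6.1 in CX3CR1low samples. A loss of short RNA in these samples would spare the long host transcripts, but 13 of 14 host genes were lower, with an upper quartile of -0.191, and 109 microRNA genes of like level had a median of -0.005, though their sample medians were also lowest in CX3CR1int samples (6.11 and 6.1, against 6.16 to 6.36). A loss of short RNA alone would thus not lower the host genes, but such a loss beside another cause stays open. Whether the microRNA signals came from short RNA was not tested. A lower share of nuclear RNA, as from leaky or damaged nuclei, could also lower both the small nucleolar RNAs and their host genes. The 8 other long nuclear RNAs had a median of -0.174 and an upper quartile of 0.002. With 5 of those 8 lower, and Malat1 at -0.21 and Neat1 at -0.63, a loss of nuclear RNA and lower production in CX3CR1int cells cannot be told apart.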
